A study of Mus musculus with 4 samples.

How the data were processed

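Gene expression was measured in 4 samples of mouse footpad RNA with Agilent 2-colour arrays, 2 of wild-type and 2 of Tabby mice at postnatal day 1, grouped by the sample titles. Per the labels, Cy3 held the footpad RNA and Cy5 a common reference on every array, and no dyes were swapped. A dye effect shared by all arrays cancels in the difference between groups. Spot intensity was read with Agilent Feature Extraction 9.5.1.1, per the file headers, which give mean and local background intensity for both channels. The deposited files also hold processed intensity, background-subtracted with spatial detrending and dye-normalized, per the file headers. All 4 arrays lay on 1 slide and were scanned together, so neither slide nor scan was a batch.

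The authors' deposited value table holds log10 values of 25164 probes. Its scale, centring and direction were settled from the values. Each value equals log10 of the processed Cy3 signal, minus the deviation of log10 processed Cy5 from its mean over the arrays, to within 0.000161. Higher values thus mean more footpad RNA. The column medians were 2.60 for wild type replicates 1 and 2, 2.59 for Tabby replicate 1 and 2.59 for Tabby replicate 2. This table was used as an alternative only.

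From the mean and background signals, background was corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The value tested was log2 of Cy3 over Cy5, in which the offset shrinks the changes of dim probes. Control spots and spots marked as non-uniform or population outliers (4 to 8 per array) were left out, and spots of 1 probe were averaged. A probe was tested if its Cy3 signal was well above background on both arrays of at least 1 group. This left out 14294 probes, and 2 more had too few unmarked spots, leaving 27710. Groups were compared with limma's lmFit and eBayes, without trend or robust options, and Benjamini-Hochberg adjustment at 0.05. An exact two-sided permutation test of 2 against 2 arrays cannot go below 0.333, so all p-values rest on limma's pooling of the spread over probes. Figures were drawn with matplotlib 3.10.9.

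Where a probe's Cy3 signal was not well above background on any array of a group, a bound is given. It compares the bright group's mean with the dim group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background. Both were Cy3 log2 values after loess and Aquantile, and without dye swaps the bound is open to a dye bias that differed between arrays. Fitted changes under other settings can lie below it.

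The method was tested on simulated data of 27710 probes with the fitted means and spread and 200 changed probes. For the comparison of Tabby with wild type, 46 of 50 changes of 1 on the log2 scale were recovered, and 50 of 50 changes of 2. There were 6 false calls among 152. The simulated groups had equal spread, and having more calls than the real data eased the adjustment.

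Before the data were examined, the design, the alternatives and a rule for named genes were fixed. The rule took Eda, the genes of largest change past the threshold with separated arrays, members of chosen gene lists, and Shh and Fox genes. The files hold probe IDs and sequences with no gene names, and the gene table used here could not be matched to them. The check of Eda, the gene lists, the named genes, the merging of probes of a gene and the removal of sex-chromosome genes were therefore not run. In place of the rule, the 2 called probes higher in Tabby and the 2 with the most negative fitted change are named. The alternatives tried covered background, normalization, Cy3 alone, filters, marked spots, the variance model, the deposited log10 values, the replicate number as a block, and each array left out.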

Results

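The 4 footpad RNA samples from newborn C57BL/6 mice in this series were profiled on 2-colour oligonucleotide arrays, 2 from wild-type mice and 2 from Tabby mice, all at postnatal day 1. Tabby mice carry a mutation in Eda, which encodes ectodysplasin, a ligand needed for the development of hair follicles, teeth and sweat glands. Footpad skin is where the mouse has its sweat glands, and the series was made to look for genes that depend on Eda while these glands form. Only postnatal day 1 was analysed here. Each array held footpad RNA in the Cy3 channel and 1 common reference RNA in the Cy5 channel. The reference was a pool of RNA from 11 mouse cell lines mixed with RNA of mouse embryonic stem cells. The wild-type samples were labelled male and the Tabby samples of mixed sex, so genotype and sex of the animals cannot be told apart.

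The arrays carried 42006 distinct probes, each 60 bases long. Between 27286 and 28872 of them per array gave a Cy3 signal well above background, or 65.0% to 68.7%. The median Cy3 signal lay between 110.2 and 128.3 intensity units, against 44.0 to 47.8 for the negative control spots. No spot was saturated. With 2 arrays per group, the number of arrays limits the precision. Nothing in the labels says whether the 2 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

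Footpad and reference signals differed far more than those of Tabby and wild type did. Without dye swaps, dye effects of single probes stay in these ratios and cannot be told apart from RNA differences. Loess also centred the ratios, with a median of 0.08 over the tested probes of each array. On all 4 arrays, 1971 of the 27710 tested probes were at least 4-fold above the reference, and 703 were at least 4-fold below it. For 134 of the 1971, the reference signal was well above background on no array. A further count, partly of the same probes, was of the 1174 probes with a Cy3 signal well above background on all 4 arrays and a reference signal well above background on none. Averaged over the arrays, 5161 probes (18.6%) lay more than 2-fold above the reference, 3279 (11.8%) more than 2-fold below it and 19270 (69.5%) within 2-fold. These classes were chosen after the data were seen, and none of the 3 passed limma's camera test for a shift between genotypes. The footpad-high class had a median log2 change of -0.01 (adjusted p = 0.682 with the preset correlation and adjusted p = 0.847 with an estimated correlation).

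The comparison of Tabby with wild type asks which footpad transcripts differ with the Eda mutation at this age, though sex follows genotype here. Of 27710 probes, 9 differed at an adjusted p under 0.05 by limma: 2 were higher in Tabby and 7 were lower. For each of the 9, both Tabby arrays lay on one side of both wild-type arrays, which was so for 33.1% of all probes (chance gives 33.3%). The files do not pair probe IDs with genes, so the 2 probes that rose and the 2 with the most negative fitted change are given by ID and sequence. Neither Eda nor the gene groups chosen before the data were examined could be looked up.

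Probe Z00016441-1 (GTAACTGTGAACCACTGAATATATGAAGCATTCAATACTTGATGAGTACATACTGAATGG) was higher in Tabby. Its log2 ratio to the reference was -4.66 ± 0.20 in wild type and 1.21 ± 0.05 in Tabby (SD, n = 2 each), and the limma adjusted p was 1.46e-05. Its Cy3 signal was not well above background on either wild-type array, so Tabby was at least 50.1-fold higher by the values after loess and Aquantile. Other settings gave fitted log2 changes below and above that bound, from 5.49 in Cy3 alone after quantile normalization to 10.52 with the scanner software's processed signals. The reference signal of this probe was well above background on all 4 arrays.

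Probe Z00017323-1 (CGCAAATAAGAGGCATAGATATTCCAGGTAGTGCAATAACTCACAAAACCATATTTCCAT) was the other one higher in Tabby. Its log2 ratio was -1.82 ± 0.09 in wild type and -0.73 ± 0.04 in Tabby (SD, n = 2 each; limma adjusted p = 0.0364). It too was not well above background on either wild-type array, and Tabby was at least 2.08-fold higher by the same rule, with fitted log2 changes from 1.005 to 4.15 over the alternatives. Its adjusted p by limma was 0.298 with the scanner software's processed signals. The probe was called in 13 of the 18 alternatives that tested it, and in neither of those that left out a Tabby array. Its lowest limma adjusted p, 1.6e-06, came from median centring, where 1 spread served all probes. The log2 change was 1.06 without Tabby replicate 1 and 1.12 without Tabby replicate 2.

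Probe Z00020870-1 (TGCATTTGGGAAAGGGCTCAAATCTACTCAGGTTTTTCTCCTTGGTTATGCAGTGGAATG) was lower in Tabby and well above background on all 4 arrays. Its log2 ratio was 3.61 ± 0.0029 in wild type and 0.47 ± 0.24 in Tabby (SD, n = 2 each). The log2 change was -3.14 with an SE of 0.13 (limma adjusted p = 8.29e-04), so that wild type was 8.80-fold higher in this fit. The reference signal of this probe also differed, by -0.45 in Cy5 alone (log2, Tabby minus wild type). In Cy3 alone, processed signals over the 75th percentile gave a change of -4.17, and the background-subtracted Cy3 signal was 978.1 ± 108.2 in wild type and 56.4 ± 7.5 in Tabby (SD, n = 2 each), or 5.76% of wild type. With the scanner software's processed signals the change was -3.15, with a limma adjusted p of 0.102, the highest of its 19 alternatives; the lowest was 6.99e-59, from median centring, where 1 spread served all probes.

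Probe Z00077373-1 (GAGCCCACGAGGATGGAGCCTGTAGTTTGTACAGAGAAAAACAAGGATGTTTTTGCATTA) was lower in Tabby. Its log2 ratio was 2.43 ± 0.31 in wild type and 0.09 ± 0.04 in Tabby (SD, n = 2 each; limma adjusted p = 0.00673). Its Cy3 signal was not well above background on either Tabby array, and wild type was at least 4.38-fold higher by the values after loess and Aquantile. In Cy3 alone after quantile normalization the fitted log2 change was -1.95, which is less than that bound, and with processed signals it was -6.19. The fitted log2 change was -2.37 without Tabby replicate 1 and -2.31 without Tabby replicate 2. The probe was called in 13 of its 15 alternatives, and in neither of those that left out a Tabby array. Its lowest limma adjusted p was 8.33e-30, from median centring, where 1 spread served all probes.

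**Figure D1:**
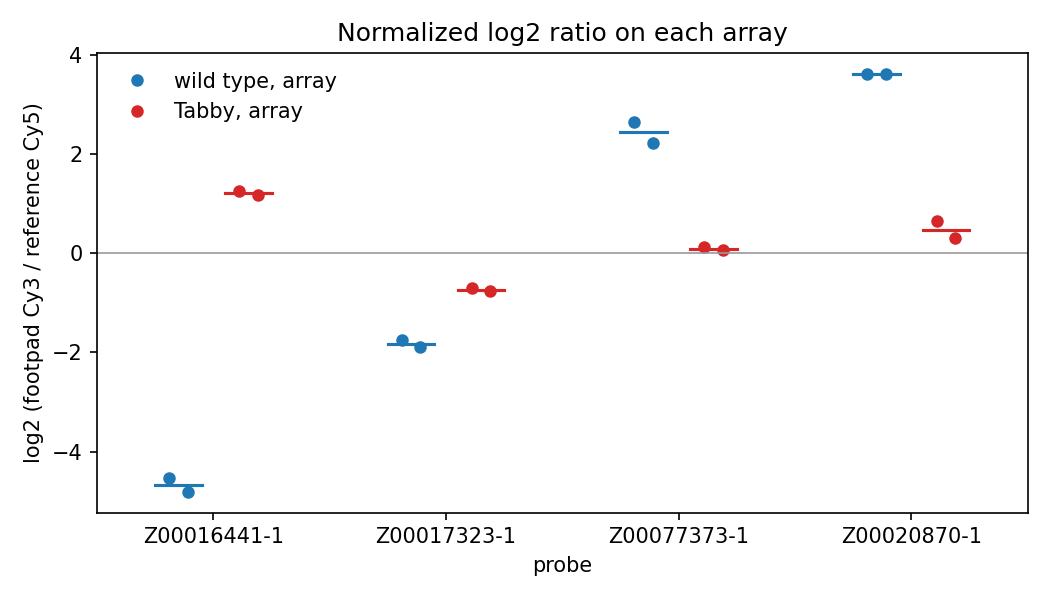
Normalized log2 ratio of footpad Cy3 to reference Cy5 (vertical axis) of the 4 probes (horizontal axis); points are single arrays, 2 wild type in blue and 2 Tabby in red, and bars are group means. Both Tabby arrays of Z00016441-1 lie above 1 and both wild-type arrays below -4.

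Of the other 5 lower probes, 4 were well above background in Tabby. Their fitted log2 changes lay between -1.86 and -1.09, with SEs of 0.088 to 0.105 and limma adjusted p between 0.00181 and 0.0364. The remaining one was at least 1.88-fold higher in wild type after loess and Aquantile (limma adjusted p = 0.0399). All 7 lower probes were above the reference in wild type, 6 of them by more than 2-fold, and 1 of the 7 was more than 2-fold above it in Tabby. The reference signal was well above background on no array for 2 of the 7, Z00077373-1 and the one still more than 2-fold above it in Tabby. For the probe with the 1.88-fold bound it was so on 1 array. The ratios of these probes are thus set against a reference near background. On 2 of the 7, the Cy3 signal was not well above background on either Tabby array. Both probes higher in Tabby were more than 2-fold below the reference in wild type.

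**Figure D2:**
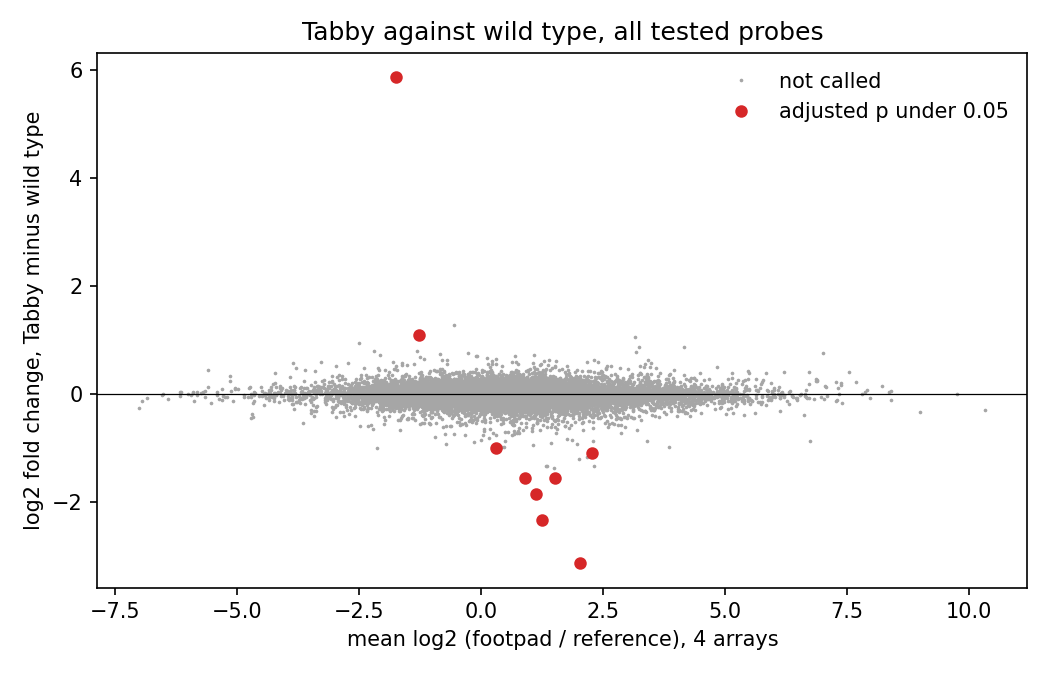
Log2 fold change, Tabby minus wild type (vertical axis), against the mean log2 ratio of footpad to reference over the 4 arrays (horizontal axis) for the 27710 tested probes; grey points were not called and the 9 red points had an adjusted p under 0.05. The 2 called higher in Tabby lie at negative mean ratios and the 7 called lower at positive ones.

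A fitted change of at least 2-fold was seen for 17 of all tested probes, the 9 called ones and 8 others, of which 2 were higher and 6 lower in Tabby. At an unadjusted p under 0.05, limma gave 1248 probes, where 1385.5 are expected by chance. Leaving out 1 array moved this count to either side of chance, to 2708 without wild type replicate 1, 6215 without wild type replicate 2, 482 without Tabby replicate 1 and 471 without Tabby replicate 2. On simulated arrays with the fitted spread, limma recovered 46 of 50 changes of 1 on the log2 scale and 0 of 50 changes of 0.5. Changes of 0.5 on this fitted scale were thus not detectable with 2 arrays per group. The simulation held 200 changed probes and gave both groups equal spread. With only 9 calls the adjustment is stricter, so the recovery of changes of 1 does not carry over to these data.

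The count depended on the handling of the signals and on single arrays. The scanner software's processed signals gave 1 higher and 2 lower, and 2 of the 9 probes were again called. The Cy3 channel alone gave 11 higher and 8 lower after quantile normalization and 10 higher and 14 lower after scaling to the 75th percentile. Median centring gave 23 higher and 42 lower, in a fit that used 1 common spread for all probes. Leaving out 1 array gave 160 probes without wild type replicate 1 and 1703 without wild type replicate 2. It gave 2 without Tabby replicate 1 and 4 without Tabby replicate 2.

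Wild type replicate 1 stood apart from the other 3 arrays on the first principal component, which held 54.9% of the variance. The difference between the 2 wild-type arrays had an SD of 0.226 over probes (log2), against 0.139 for the 2 Tabby arrays. Pairs of arrays correlated between 0.986 and 0.995 across probes, which are not independent replicates.

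The common reference served as a control, since the same RNA lay on every array. In the Cy5 channel alone limma called 0 probes between the arrays of the genotypes, and 740 had an unadjusted p under 0.05. The mean Cy5 difference was 0.22 (log2, 287 probes) in the last of the 85 array columns. The Cy3 difference there was 0.23 and that of the log2 ratio 0.05.

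**Figure D3:**
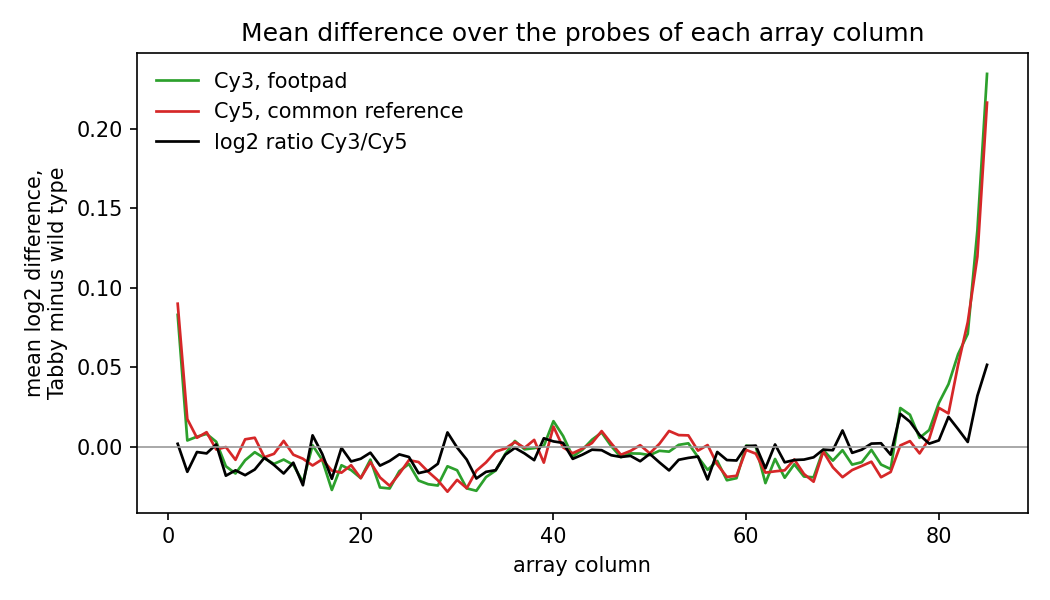
Mean log2 difference, Tabby minus wild type (vertical axis), over the tested probes of each array column (horizontal axis) for footpad Cy3 (green), reference Cy5 (red) and their log2 ratio (black). Both channels rise together in the last columns, to 0.23 and 0.22, and the ratio reaches 0.05.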

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

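The settings without the outermost 5 columns were chosen after seeing the data. All 9 called probes kept their direction under every setting that measured them, but many settings could not have changed it. All 9 had both Tabby arrays on one side of both wild-type arrays, so leaving out 1 array keeps the sign. The filters, Aquantile, trend with robust, the replicate block and removal of the outermost columns leave the fitted change as it is. No background subtraction, Aquantile (which leaves ratios as they are), no filter, marked spots kept, an adjusted p under 0.1 and a minimum change of 1 (log2) gave 9 calls, and trend with robust gave 8. Leaving out the outermost columns gave 8.

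Other settings gave these counts of changed, higher and lower probes, and the cause was not tested unless given. Processed signals gave 3, 1 and 2. Cy3 alone gave 19, 11 and 8 after quantile normalization, 24, 10 and 14 after 75th percentile scaling, and without the outermost columns 6, 2 and 4 after quantile normalization and 20, 7 and 13 after 75th percentile scaling. The stricter filter, which removed 6 of the 9 called probes, gave 3, 0 and 3. The deposited log10 values gave 6, 1 and 5. Median centring gave 65, 23 and 42, and its prior degrees of freedom were infinite, so 1 spread served all probes. Leaving out 1 array gave 2 to 1703 changed, 1 to 742 higher and 1 to 961 lower. The lone array is then assumed to vary like the other group, and without a wild-type array the spread comes from the closer Tabby pair.

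The replicate block gave 23, 2 and 21, with all 9 calls shared. The labels show no pairing behind the numbers, and same-numbered arrays deviated with a correlation of 0.0453 over probes. Of the 4 named probes, Z00016441-1 was called in all 18 settings that tested it, Z00020870-1 in 17 of 19, Z00077373-1 in 13 of 15 and Z00017323-1 in 13 of 18. Not run, for want of gene names, were the alternatives for Eda, the gene lists (estimated correlation, fry), single probes per gene and sex-chromosome genes. Low signal over background leaves only bounds for 4 of the 9.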

Other observations

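The settings without wild type replicate 1, with Cy3 alone over all columns and with median centring were planned before the data were examined. What each test below was to show was set after its result or related values had been seen, except for wild type replicate 1 on the share of lower probes. The settings without the outermost columns and the tests of array position were chosen after the result was seen. A test of sex-linked genes was planned but not run.

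Probes that overlap in sequence gave like results. Among tested probes, 788 pairs shared at least 25 bases, and their log2 changes had a Spearman correlation of 0.811 across pairs, which are not independent. None of the 9 called probes had such a partner (0 of 9).

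The 9 calls between Tabby and wild type were set against technical and sex effects. A position effect at the array edge was argued against, since 0.111 of the calls lay in the 5 outermost columns of either side, which hold 0.107 of tested probes; positions elsewhere were not tested. Dilution of male-only RNA by female animals in the Tabby samples was weighed as the 1 cause of all 7 falls. The same share of signal would then be left, provided each probe detected only that RNA. Among the 5 lower probes still well above background in Tabby, the highest share was 6.75 times the lowest. That proviso was not tested, so the range cannot exclude this cause, and the 2 rises were not covered. Whether single probes reflect sex or the Eda mutation cannot be told apart, since 0 called probes have a gene name and sex follows genotype; with 3 splits of the 4 arrays no share under 0.05 can be reached (1 split, the real one, gave 9 calls and the highest other 0).

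In the Cy3 channel alone, 11 probes were called higher in Tabby, against 2 by the ratio. Over all 11, chosen without the ratio, the reference channel, which holds 1 RNA, moved by a median of 0.871 of the Cy3 change, which argues against a difference between the footpad RNAs for the set as a whole. The 2 that the ratio also called are exceptions, with -0.0144 and 0.0312. Of the 11, 8 lay in the outermost columns, a share of 0.727 against 0.107 of tested probes. An effect of position at the array edge may therefore account for these 8.

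At an unadjusted p under 0.01, 214 probes were lower and 79 higher in Tabby, a total of 293 where 277.1 are expected in theory. The other 2 splits of the 4 arrays gave 111 and 120 such probes, 45.0% and 36.7% of them lower, and leaving out 1 array gave totals from 102 without Tabby replicate 1 to 3000 without wild type replicate 2. The excess of lower ones is not settled. Without wild type replicate 1 the share lower was 0.691, so an excess was also seen without that array, while without wild type replicate 2 it was 0.55. Either fit rests on 1 wild-type array and the spread of the Tabby pair, and selects other probes. Neither can thus isolate the part of wild type replicate 1. In Cy3 alone the share was 0.530 after quantile normalization and 0.505 after 75th percentile scaling, but 0.681 and 0.636 without the outermost columns. The planned settings over all columns thus went with the divisor as a cause. Those without the outermost columns went against it as the whole cause, in the second setting narrowly, but were chosen after the result was seen. The part of the divisor thus stays open. Median centring gave 0.551, but that fit also used 1 common spread for all probes. It thus cannot decide on the loess normalization by itself, which stays open. A hypothesis that the lower transcripts are those the footpad holds above the reference found no backing as a cause of the excess. The share more than 2-fold above the reference was 42.1% of lower and 41.8% of higher probes, a difference of 0.00284. Both lay above the 18.6% of all tested probes, so the trait was common to both directions.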
